A study of Mus musculus with 12 samples.

How the data were processed

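RNA from mouse colorectal cancer tissue was measured on 12 single-colour whole-transcript arrays, 3 for each of 4 groups. Tumours had been grown in healthy or in fatty liver, and the mice had received vehicle or an antibody treatment named anti-VEGF in the labels. Each group held 3 mice per the series' design text, and the labels call the replicates biological. Per the labels' protocols, total RNA was extracted, checked for integrity, purified, treated with DNase, amplified and labelled with biotin. The submitters' processing notes name Affymetrix Expression Console, and its version, the summarisation algorithm and the genome build are not given in the sources used here.

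The values analysed are the log2 expression values the authors deposited, 1 column per array. Their quartiles were nearly equal in all columns, and how the authors normalized them is not given in the sources used here. The log2 scale was read from the range of the values and is not stated in the sources used here; whether values were centred is not stated either, and a direction does not arise because each array holds 1 sample. The medians of the 3 columns of the healthy liver vehicle group were 4.92, 4.95 and 4.92, and those of the healthy liver anti-VEGF group 4.95, 4.93 and 4.95. For fatty liver they were 4.90, 4.95 and 4.93 under vehicle and 4.99, 4.91 and 4.88 under anti-VEGF. No further normalization was applied for the main results. No column of another series was present. No scanner background or detection call was used, so the number of arrays and the signal over background limit the precision, and neither depth nor counting error applies.

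Gene names came from the platform annotation supplied with the data, which lists 1 symbol for 23521 rows, several for 1814 and none for 16010. Of the rows with 1 symbol, 23328 matched a gene number in the RefSeq gene table and 0 symbols changed. Rows with several symbols or none were left out of the gene tests, and no coordinates are given because no build is named. For the 1082 genes with several rows, the row with the highest mean over the 12 arrays stood for the gene, which left 22180 genes. A gene was tested when its value lay above the median of the whole table, 4.93, on at least 3 arrays, which left 13286 genes. A group mean below that limit was taken as not distinguishable from background, and a difference from it can understate the true change.

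All 12 arrays entered 1 limma model (version 3.58.1, R version 4.3.3) with a mean per group, lmFit and eBayes, with 8 residual degrees of freedom and 2.40 prior degrees of freedom. The 5 contrasts were anti-VEGF against vehicle in each liver, fatty against healthy liver under each treatment, and the interaction of liver and treatment. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and errors given with log2 differences are moderated standard errors (SE). Adjusted p-values of single genes are from limma. Before the data were examined, 32 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The 29 lists with at least 5 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, again with a correlation estimated per list, and with fry. Measured members are those among the tested genes. Counts within a list are given over all genes tested and, separately, adjusted over the list alone. The cholangiocyte, erythroid and acinar pancreas lists had 2, 4 and 3 measured members and were not tested.

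The naming rule took, per contrast, the 10 genes past the threshold with the largest rise and the 10 with the largest fall, leaving out predicted, clone-named and segment-family symbols. Where none passed in a direction, it took the 5 with the smallest p. It added up to 4 members of each described list by smallest p, and a fixed set of genes where measured, including Vegfa, Kdr, Flt1, Cpt1a, Cd36, Slc2a1, Car9, Alb and Mki67. Alb was below the limit on every array and was not tested.

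Replicate numbers are shared between groups in the labels. Deviations from the group means of same-numbered arrays correlated above 0.1 in all 3 pairs only between the vehicle groups of the 2 livers, at 0.536, 0.701 and 0.549. That pairing comes from the data alone, and arrays 1 and 3 of these groups correlated as well across numbers, at 0.553 and 0.574. With the replicate number as a block, 6671 genes passed in that comparison, and 7181 in a blocked fit of the 6 vehicle arrays alone.

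The fit was tested on simulated data for the same 13286 genes with the observed means and residual spreads. Noise was drawn independently for each gene and array, so deviations shared across genes on an array were absent. The shares recovered and the false calls hold for such data only. For anti-VEGF against vehicle in healthy liver it recovered 93.9% of genes changed by 2 on the log2 scale, 70.1% of those changed by 1 and 38.8% of those changed by 0.5, with 12 false calls. The corresponding shares for the interaction were 92.4%, 55.2% and 8.96%, with 4 false calls.

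The alternatives varied the filter, the normalization, the variance model, array weights, the arrays in the fit, the replicate block, the threshold, covariates and the set test. They also left out each replicate in turn. Alternatives chosen after seeing the data left out arrays that stood apart or were high in Xist, averaged near-identical arrays, used the fibroblast and matrix list as a covariate, or fitted the replicate block in the vehicle arrays alone.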

Results

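Gene expression was measured on arrays in mouse colorectal cancer tissue grown in the liver. The design crossed the state of the liver, healthy or fatty, with treatment, vehicle or anti-VEGF, an antiangiogenic agent directed at vascular endothelial growth factor. There were 4 groups, each of 3 mice per the series' design text. The comparisons ask how the tumour tissue differs between livers, how it differs with treatment, and whether the treatment difference depends on the liver.

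The first principal component of the 13286 tested genes held 76.2% of the variance and separated the livers, with 2 arrays lying between the others, vehicle array 2 of healthy liver at -4.96 and anti-VEGF array 3 of fatty liver at 9.26. Vehicle array 2 of healthy liver had an endothelial list mean of 8.77 on the log2 scale, against 5.59 and 5.62 on the other vehicle arrays of healthy liver. Its fibroblast and matrix list mean was 10.41, against 8.16 and 8.13. In fatty liver, vehicle array 2 and anti-VEGF array 1 also had high endothelial list means, 7.44 and 6.91, and anti-VEGF array 3 had the lowest T and NK cell list mean of the fatty liver arrays, 5.67. Other arrays of 1 group were nearly alike. The SD of the difference over the 13286 tested genes was 0.163 between vehicle arrays 1 and 3 of healthy liver and 0.163 between those of fatty liver. It was 0.148 to 0.156 among the 3 healthy liver anti-VEGF arrays. The remaining pairs within groups ranged from 0.391 to 0.636. Each array was counted as a replicate, as labelled. The values cannot show whether the nearly alike arrays came from separate mice. If they did not, the SDs, standard errors and counts of genes given below rest on fewer independent samples than stated. Xist, the RNA that silences an X chromosome in female cells, was above the limit on vehicle arrays 1 and 3 of both livers, at 8.10 or higher, and at most 4.32 on the other 8 arrays, so no anti-VEGF array was high in it. On those vehicle arrays Xist averaged 2.25 higher in fatty than in healthy liver, and the mean of 3 Y-linked genes on the anti-VEGF arrays was 4.74 to 5.02 in healthy and 7.20 to 7.97 in fatty liver.

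**Figure D1:**
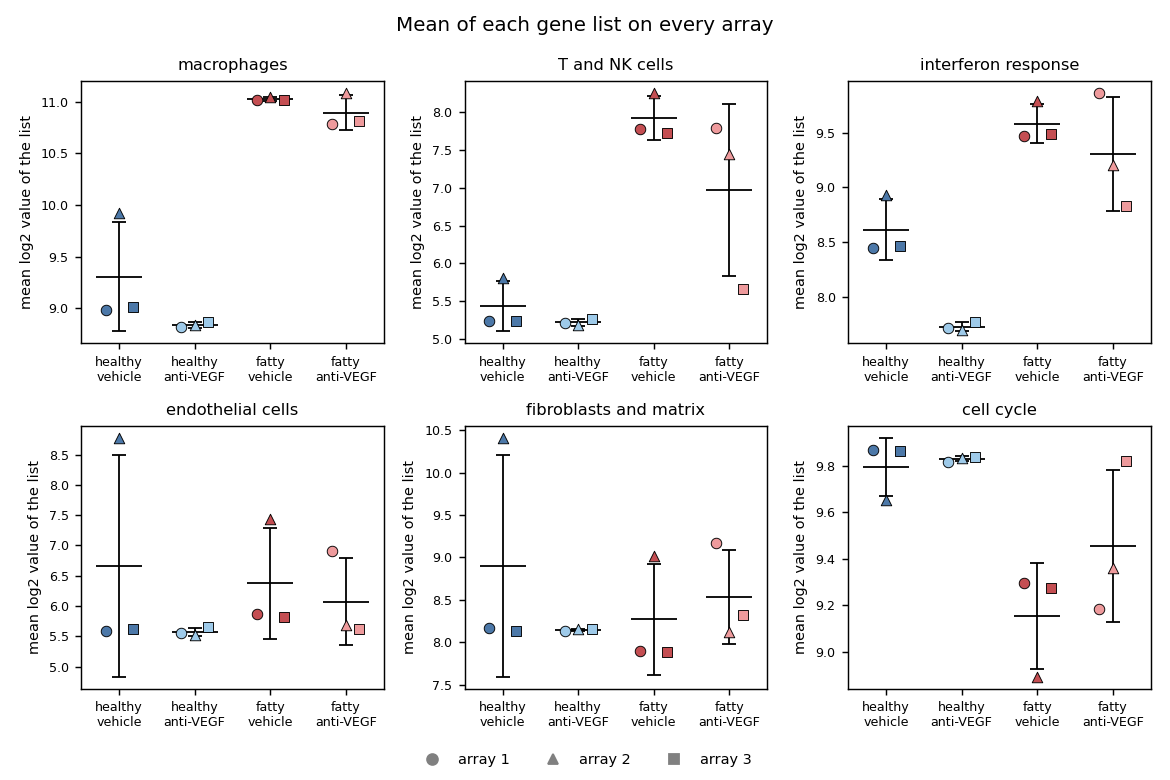
Mean log2 value (vertical axis) of the measured members of 6 gene lists on each array, by group (horizontal axis); symbols mark the replicate number, and bars the group mean with its SD (n = 3). Macrophage list means of all 6 fatty liver arrays, 10.78 to 11.09, lie above the highest healthy liver array, 9.92.

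Under vehicle, tumours in fatty liver carried more macrophage and T and NK cell transcripts than tumours in healthy liver. Transcripts of the cell cycle and of sterol and fatty acid synthesis were fewer. Whether a lower share of tumour cells in the samples accounts for these falls was not tested. Of the 18 measured macrophage genes 17 rose, with a median log2 difference of 1.84, and all 23 measured T and NK cell genes rose, with a median of 2.37. Ncr1, an activating receptor of NK cells, went from 4.43 ± 0.03 to 8.97 ± 0.26 (log2, SD, n = 3), and Csf1r, the receptor for macrophage colony-stimulating factor, from 8.44 ± 0.83 to 10.91 ± 0.13. In all, 6595 genes passed in limma at an adjusted p of 0.05, 2550 higher and 4045 lower in fatty liver. The median log2 difference of all tested genes was -0.12, and it was not subtracted from the differences given.

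Among the 10 largest rises were genes of cytotoxic lymphocytes: Ncr1 (log2 difference 4.54, SE 0.92, adjusted p = 0.0032), the granzymes Gzmc (4.52, SE 0.89) and Gzma (3.81, SE 0.75), and Klrd1, a receptor subunit of NK cells (4.20, SE 0.73). The healthy liver means of Ncr1, Klrd1 and Gzma lay below the limit. Among the largest falls were Pcdhb18, a protocadherin (-1.94, SE 0.47), the transcription factor gene Osr2 (-1.58, SE 0.21) and Mmp2, a protease that degrades matrix (-1.57, SE 0.42). In the T and NK cell list, Cd4 rose by 2.04 (SE 0.24) and Klrk1 by 3.67 (SE 0.54). All 23 genes also passed adjusted over the list alone, and camera gave the list an adjusted p of 6.94e-11 (adjusted p = 0.52 with an estimated correlation). Macrophage genes included Itgam (2.31, SE 0.25) and Csf1r (2.47, SE 0.31); 18 of 18 rose adjusted over the list alone, with the same camera p (adjusted p = 0.52 with an estimated correlation). In the antigen presentation list 11 of 14 genes rose, among them H2-Aa (2.25, SE 0.34), also 11 adjusted over the list alone (camera adjusted p = 2.88e-06; adjusted p = 0.52 with an estimated correlation). Interferon response genes rose in 16 of 24 cases, 17 adjusted over the list alone. They included Irf7 (1.74, SE 0.28) and Mx1 (2.51, SE 0.42), a factor against viruses (camera adjusted p = 3.25e-06; adjusted p = 0.68 with an estimated correlation). Neutrophil genes rose in 6 of 11 cases, 7 adjusted over the list alone, including the collagenase Mmp8 (3.57, SE 0.51; camera adjusted p = 0.00051; adjusted p = 0.68 with an estimated correlation). The immediate early list had 8 of 17 genes up and Myc down (-0.62, SE 0.14), and adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.00959; adjusted p = 0.68 with an estimated correlation). In the list of sinusoidal and lymphatic endothelium 5 of 7 genes rose, 5 adjusted over the list alone, such as Mrc1, also a macrophage gene (1.49, SE 0.26), and Dnase1l3 (1.60, SE 0.31; camera adjusted p = 0.00959; adjusted p = 0.68 with an estimated correlation). Of 5 Kupffer cell genes 3 rose, 3 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0505). B and plasma cell genes went both ways, with 4 of 7 up and 3 down, and camera did not call that list either.

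Lipid genes went both ways. In the list of fatty acid uptake, transport and lipid droplets, 10 of 22 genes rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00959; adjusted p = 0.42 with an estimated correlation). The number falling was 1 without healthy liver vehicle array 1 or 3 or fatty liver vehicle array 2. Plin2, which coats lipid droplets, rose by 1.18 (SE 0.11) and the lipase Lpl by 2.25 (SE 0.38). Increases were also seen for Fabp5, a carrier of fatty acids, by 2.49 (SE 0.32), and Cd36, a fatty acid transporter, by 2.71 (SE 0.66). The adipocyte list had 4 of 8 genes up, 4 adjusted over the list alone, led by the nuclear receptor Pparg (2.46, SE 0.23; camera adjusted p = 0.0106; adjusted p = 0.42 with an estimated correlation). Pparg, Lpl and Cd36 are also active in macrophages. In fatty acid synthesis 10 of 15 genes fell and 1 rose, the same adjusted over the list alone, with Me1 at -1.44 (SE 0.23) and the synthase Fasn at -0.96 (SE 0.19; camera adjusted p = 0.0158; adjusted p = 0.68 with an estimated correlation). Of these, 6 fell without healthy liver vehicle array 1 or 3 or fatty liver vehicle array 2. Cholesterol synthesis genes fell in 14 of 16 cases, 15 adjusted over the list alone, among them Cyp51 (-0.75, SE 0.14) and Sc5d (-0.63, SE 0.12; camera adjusted p = 0.00156; adjusted p = 0.68 with an estimated correlation). Of the fatty acid oxidation list, 4 of 23 genes rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.579), with 1 or 2 rising without healthy liver vehicle array 1 or 3 or any of the fatty liver vehicle arrays. The number falling was 1 without healthy liver vehicle array 1 or 3 or fatty liver vehicle array 2 or 3, and 5 without fatty liver anti-VEGF array 1. Cpt1a, which admits fatty acids to mitochondria, was higher by 0.49 (SE 0.16, adjusted p = 0.0291), a call lost without healthy liver vehicle array 1 or 3 or any of the fatty liver vehicle arrays.

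Cell cycle genes fell in 24 of 29 cases, 27 adjusted over the list alone, such as Cdc20 (-1.02, SE 0.20) and Rrm2 (-0.85, SE 0.15; camera adjusted p = 3.94e-05; adjusted p = 0.68 with an estimated correlation). The number was 14 without fatty liver vehicle array 2. With near-identical arrays averaged, 0 genes of the cell cycle, 0 of cholesterol synthesis and 0 of fatty acid synthesis fell. Then 6 macrophage, 4 T and NK cell, 4 antigen presentation, 1 interferon, 1 neutrophil, 0 immediate early and 3 fatty acid uptake genes rose. So did 0 genes of sinusoidal and lymphatic endothelium, 1 of Kupffer cells and 2 of adipocytes, and 0 fibroblast and matrix genes and 1 pericyte gene fell. Mki67, a marker of dividing cells, did not pass (-0.39, SE 0.17, adjusted p = 0.0776). Of 21 fibroblast and matrix genes 8 fell, 8 adjusted over the list alone, among them Pdgfra (-1.22, SE 0.23) and Col5a1 (-1.07, SE 0.20; camera adjusted p = 0.0784). Of 13 pericyte and smooth muscle genes 4 fell, 4 adjusted over the list alone, including Pdgfrb (-1.22, SE 0.16) and Acta2 (-0.76, SE 0.14; camera adjusted p = 0.469). In the endothelial list 1 gene, Kdr, rose (2.10, SE 0.75, adjusted p = 0.0386) and 1 fell, 0 and 0 adjusted over the list alone (camera adjusted p = 0.899). Kdr was not called in 9 of the 12 fits that leave out 1 array, and 3 endothelial genes rose without healthy liver vehicle array 2. Of 29 hypoxia response genes 7 rose and 4 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.629), and 3 rose without fatty liver vehicle array 2. The number falling was 7 without fatty liver anti-VEGF array 1 or 3. It was 2 without healthy liver vehicle array 1 or 3, any healthy liver anti-VEGF array or fatty liver vehicle array 2 or 3. Vegfa was higher by 0.43 (SE 0.12, adjusted p = 0.0128), a call lost without fatty liver vehicle array 2. Car9 did not pass (0.05, SE 0.23, adjusted p = 0.887). The count of genes past the threshold was 721 with near-identical arrays averaged and, with 1 array left per liver, 1057 without the 4 vehicle arrays high in Xist, where the lone arrays are assumed to vary like the anti-VEGF groups. With the hepatocyte list as a covariate it was 1074. Only 8 of that list's 34 genes were measured and Alb stayed below the limit. The lower count therefore does not show that hepatocytes account for the difference between livers.

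**Figure D2:**
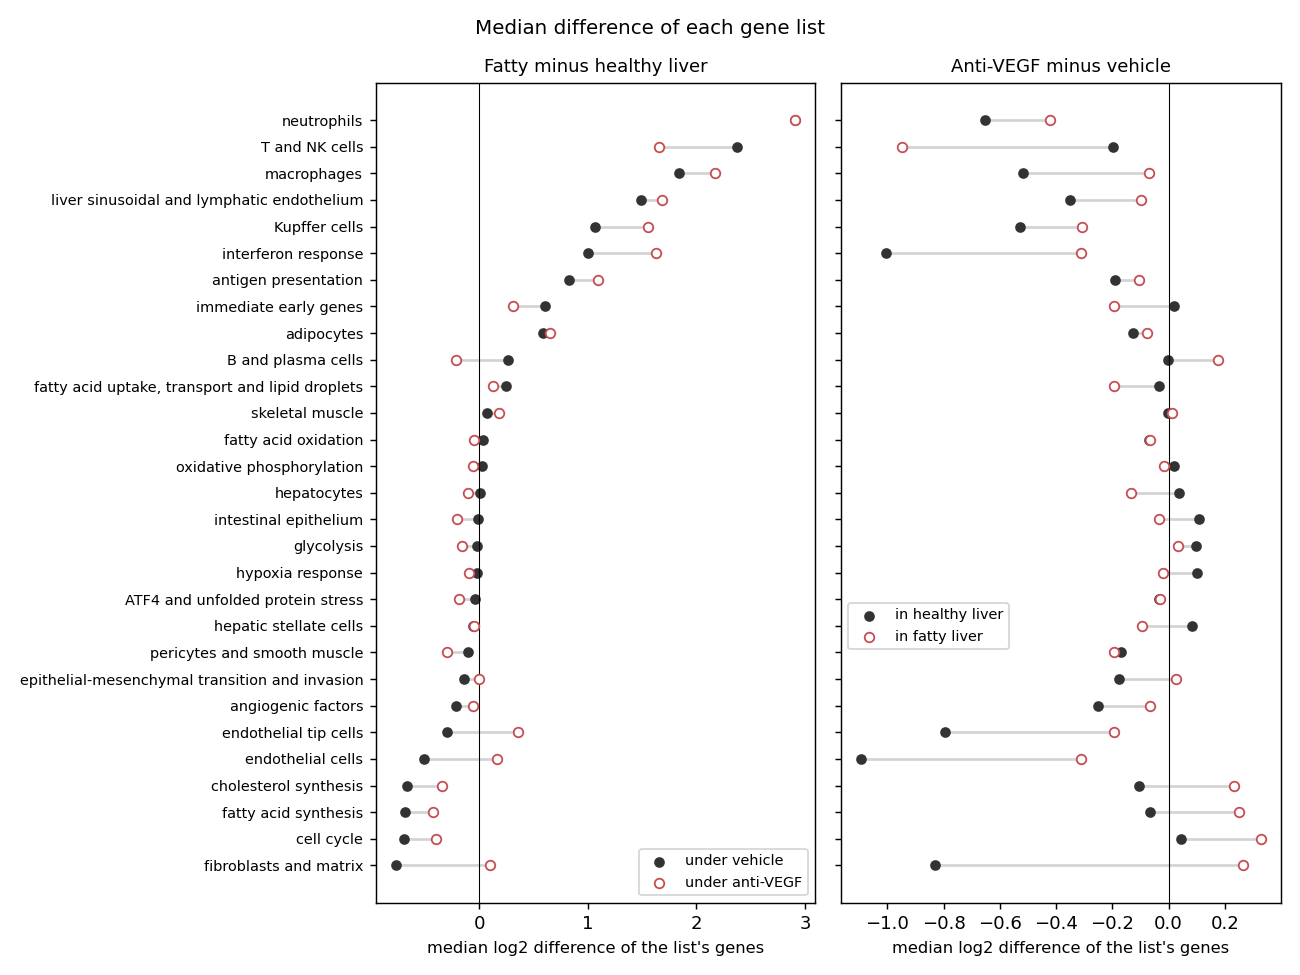
Median log2 difference (horizontal axis) of the measured genes of each of the 29 tested lists (vertical axis), fatty minus healthy liver on the left and anti-VEGF minus vehicle on the right; filled and open points are the conditions named in each key. The T and NK cell list lies at 2.37 under vehicle and 1.66 under anti-VEGF on the left.

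Under anti-VEGF, macrophage, interferon, antigen presentation and neutrophil genes were again higher in tumours of fatty liver. Of the macrophage list 17 of 18 genes rose, with a median log2 difference of 2.17, and of the interferon response list 23 of 24, with a median of 1.63. Itgam, an integrin of myeloid cells, went from 8.67 ± 0.02 to 11.60 ± 0.18, and Irf7, a regulator of the interferon response, from 8.89 ± 0.10 to 11.45 ± 0.37 (log2, SD, n = 3). In limma 6084 genes passed, 2412 higher and 3672 lower, around a median of all genes of -0.13.

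The 10 largest rises included Sirpb1c (4.47, SE 0.42, adjusted p = 4.52e-05), Mmp8 (4.29, SE 0.51), the receptor Adgre4 (4.19, SE 0.27) and Acod1, which makes itaconate in activated macrophages (4.05, SE 0.75). The healthy liver mean of Adgre4 lay below the limit. Falls included Sele, an adhesion molecule of activated endothelium (-1.99, SE 0.29), and the matrix protein gene Ccn1 (-1.54, SE 0.20). Adjusted over the list alone, 17 macrophage genes and 23 interferon genes rose (camera adjusted p = 1.07e-12 and 1.4e-11; adjusted p = 0.33 and 0.40 with an estimated correlation). In the antigen presentation list 12 of 14 genes rose, 12 adjusted over the list alone, such as Tap1, a peptide transporter (1.19, SE 0.16; camera adjusted p = 4.6e-08; adjusted p = 0.33 with an estimated correlation). Neutrophil genes rose in 6 of 11 cases, 8 adjusted over the list alone, including Csf3r (3.47, SE 0.36; camera adjusted p = 0.000264; adjusted p = 0.62 with an estimated correlation); without fatty liver anti-VEGF array 3, 10 rose. T and NK cell genes rose in 19 of 23 cases, 22 adjusted over the list alone, with Cd4 at 1.72 (SE 0.24) and Klrk1 at 2.92 (SE 0.54; camera adjusted p = 5.49e-08; adjusted p = 0.61 with an estimated correlation). Their spread was wide, since fatty liver anti-VEGF array 3 lay near the healthy liver arrays, and 11 rose without either of the other fatty liver anti-VEGF arrays and 12 without healthy liver anti-VEGF array 2. The Kupffer cell list had 3 of 5 genes up, 3 adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.33 with an estimated correlation). The list of sinusoidal and lymphatic endothelium had 4 of 7, 5 adjusted over the list alone (camera adjusted p = 0.00726; adjusted p = 0.59 with an estimated correlation). The members of these that rose included Nr1h3 (1.55, SE 0.20), Folr2 (1.85, SE 0.29), Mrc1 (1.79, SE 0.26) and Dnase1l3 (2.45, SE 0.31), of which Folr2 and Mrc1 are also macrophage genes. Of 7 B and plasma cell genes 3 rose and 3 fell.

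Plin2 rose by 1.32 (SE 0.11), Lpl by 2.97 (SE 0.38), Fabp5 by 2.92 (SE 0.32), Cd36 by 3.14 (SE 0.66) and Cpt1a by 0.72 (SE 0.16). In their list of uptake and storage 8 of 22 genes rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0378; adjusted p = 0.33 with an estimated correlation). Camera's call was lost without fatty liver anti-VEGF array 1. The number falling was 4 without fatty liver anti-VEGF array 3 and 2 without its array 1 or fatty liver vehicle array 1 or 2. Of 8 adipocyte genes 5 rose and 1 fell, the same adjusted over the list alone, with Pparg at 3.34 (SE 0.23; camera adjusted p = 0.00775; adjusted p = 0.33 with an estimated correlation). Fatty acid synthesis had 4 of 15 genes down, among them Me1 (-0.96, SE 0.23), and 1 up, Slc25a1 (0.83, SE 0.12), the same adjusted over the list alone (camera adjusted p = 0.401). Cholesterol synthesis had 2 of 16 down, 1 adjusted over the list alone (camera adjusted p = 0.232), and 4 without healthy liver vehicle array 2. The cell cycle had 6 of 29 down, 6 adjusted over the list alone, such as Cdc20 (-0.74, SE 0.20; camera adjusted p = 0.0181; adjusted p = 0.91 with an estimated correlation). Without fatty liver anti-VEGF array 3, whose cell cycle mean of 9.82 lay within the range of the healthy liver arrays, 24 cell cycle, 10 cholesterol and 10 fatty acid synthesis genes fell. Without any 1 of the other 5 anti-VEGF arrays, 1 to 3 cell cycle genes, 1 cholesterol gene and 2 fatty acid synthesis genes fell, and camera did not call the cell cycle list without fatty liver anti-VEGF array 1. Pecam1, an adhesion molecule of endothelial cells, rose by 2.75 (SE 0.71) and Kdr by 3.12 (SE 0.75), the 2 of 19 endothelial genes that passed, 2 adjusted over the list alone (camera adjusted p = 0.382). Of 29 hypoxia response genes 4 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.872). The number falling was 13 without fatty liver anti-VEGF array 3 and 4 without its array 1 or any healthy liver anti-VEGF array. Vegfa did not pass (0.19, SE 0.12, adjusted p = 0.213). The count of genes past the threshold was 510 with near-identical arrays averaged and 9884 with array weights. With that averaging 10 macrophage, 2 interferon, 2 antigen presentation, 2 neutrophil, 1 Kupffer cell and 0 T and NK cell genes rose. In the list of sinusoidal and lymphatic endothelium 0 rose, and 0 cell cycle genes fell.

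**Figure D3:**
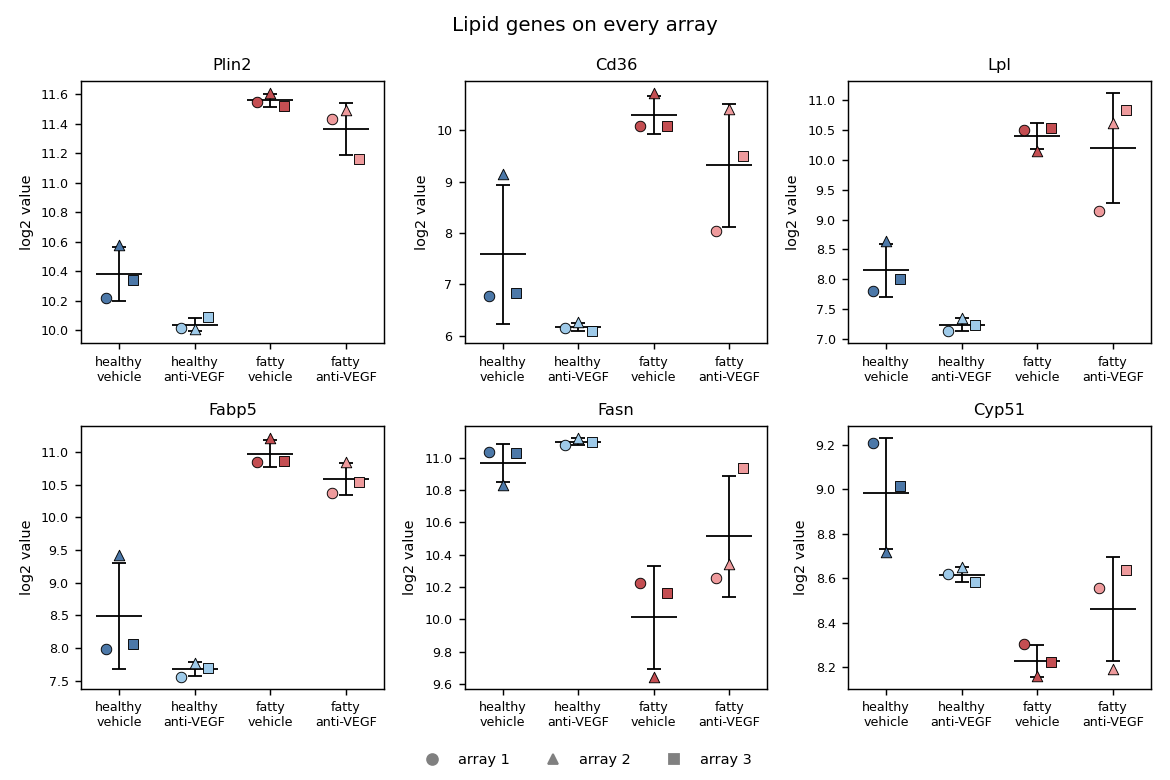
Log2 values (vertical axis) of 6 lipid genes on each array, by group (horizontal axis); symbols mark the replicate number, and bars the group mean with its SD (n = 3). Plin2 averaged 10.38 and 10.04 in healthy liver and 11.56 and 11.36 in fatty liver, under vehicle and anti-VEGF.

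The 2 comparisons between livers share no array. Of the genes that passed, 2086 were higher and 2903 lower in both, against 463 and 1118 for independent lists, and 4 passed in opposite directions.

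In healthy liver, interferon response genes were lower under anti-VEGF than under vehicle as a list, while no single gene passed among all genes. The median log2 difference of the 24 measured members was -1.01, 23 of them were lower, and adjusted over the list alone 20 passed, against 0 over all genes. Camera gave the list an adjusted p of 1.54e-22 (adjusted p = 0.58 with an estimated correlation). Examples that did not pass over all genes were Oasl2 (-1.13, SE 0.20, adjusted p = 0.109), Irf9 (-0.72, SE 0.13, adjusted p = 0.109) and Bst2, which tethers viruses (-0.88, SE 0.14, adjusted p = 0.106).

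No gene passed in limma, with a smallest adjusted p of 0.0605, and 1118 genes had an unadjusted p under 0.05. The genes with the smallest p included Cfap57 (0.99, SE 0.12) and Ndrg2 (0.92, SE 0.14) on the higher side and Casp12 (-0.88, SE 0.11) and Rtp4, itself induced by interferon (-1.32, SE 0.19), on the lower side. By camera, 8 lists passed, 0 with an estimated correlation and 0 by fry. The macrophage list had a median of -0.52 (0 of 18 genes passed, 0 adjusted over the list alone; camera adjusted p = 5.29e-07; adjusted p = 0.58 with an estimated correlation). Without vehicle array 2 its median was -0.23 (camera adjusted p = 0.0392). Medians were -1.09 for the endothelial list (camera adjusted p = 6.37e-05), -0.80 for tip cells (0.0044), and -0.83 for fibroblasts and matrix (0.000923). They were -0.53 for Kupffer cells (0.0288), -0.19 for antigen presentation (0.00279) and 0.10 for glycolysis (0.0247). Each of these lists had adjusted p = 0.58 with an estimated correlation. These 6 calls were lost without vehicle array 2, the array rich in endothelial and matrix transcripts. Without that array the medians were 0.0022 for the endothelial list, 0.012 for tip cells, -0.042 for fibroblasts and matrix and -0.039 for antigen presentation. Without vehicle array 1 the endothelial median was -1.70. Without vehicle array 1 or 3 the medians were -1.36 or -1.31 for fibroblasts and matrix and -0.35 or -0.31 for antigen presentation. The call of Kupffer cells was lost also without anti-VEGF array 2. Vegfa differed by 0.09 (SE 0.12) and Kdr, a receptor of VEGF, by -1.89 (SE 0.75), and neither passed. The count of genes was 41 without fatty liver anti-VEGF array 1, 4 without its array 2, 31 without its array 3, 47 in a fit of the 2 groups alone and 1661 with array weights. It was 1185 in the 2 groups alone without vehicle array 2. That fit sets vehicle arrays 1 and 3, both high in Xist, against anti-VEGF arrays that are not. Host sex and treatment cannot be told apart in it, and the arrays of each side are nearly alike, which narrows its errors.

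In fatty liver, T and NK cell genes were lower under anti-VEGF as a list and cell cycle genes higher, and 1 gene passed. All 23 measured T and NK cell genes were lower, with a median log2 difference of -0.95, and 28 of 29 cell cycle genes higher, with a median of 0.33. Neither list was called over all 12 arrays with an estimated correlation (adjusted p = 0.83 for both). Without anti-VEGF array 3 these medians were -0.29 and 0.14, and without vehicle array 2 that of the cell cycle was 0.17. Vehicle arrays 1 and 3 were high in Xist and no anti-VEGF array was, and host sex was not tested for these lists. Klk1b11, a gene of the kallikrein family of proteases, fell by 1.78 on the log2 scale (SE 0.19, adjusted p = 0.0257), from 7.77 ± 0.15 to 5.99 ± 0.25 (SD, n = 3), and was 5.16 ± 0.37 and 5.01 ± 0.16 in healthy liver.

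Klk1b11 was the only call in limma, against 778 genes with an unadjusted p under 0.05, and it was lost on leaving out any of 8 of the 12 arrays, with adjusted p up to 0.251. Within the T and NK cell and cell cycle lists 0 genes passed, 0 adjusted over the list alone; Cd27, a receptor of lymphocytes (-1.06, SE 0.30), and Rrm2 (0.43, SE 0.15) each had an adjusted p of 0.795. By camera 6 lists passed, 0 with an estimated correlation and 0 by fry. They were T and NK cells (adjusted p = 1.13e-11), the cell cycle (7.08e-10), interferon response with a median of -0.31 (8.04e-05). The others were fatty acid synthesis with 0.25 (0.000479), cholesterol synthesis with 0.23 (0.000521) and fatty acid uptake with -0.19 (0.0245). With an estimated correlation the adjusted p was 0.78 for fatty acid uptake and 0.83 for the others. Anti-VEGF array 3, with few T and NK cell transcripts and the highest cell cycle mean of the group, had a share in this, while the T and NK cell mean of array 1, 7.78, lay within the range of the vehicle arrays. Without array 3 the calls of interferon response, fatty acid synthesis and fatty acid uptake were lost. Leaving out vehicle array 2 ended those of fatty acid uptake and cholesterol synthesis, and leaving out anti-VEGF array 1 that of cholesterol synthesis. Without anti-VEGF array 3 the medians were 0.12 for fatty acid synthesis, 0.12 for cholesterol synthesis, -0.11 for fatty acid uptake and -0.053 for interferon response. Without vehicle array 2 those of fatty acid and cholesterol synthesis were 0.17 and 0.14. Interferon response was at -0.59 without anti-VEGF array 1 and cholesterol synthesis at 0.38 without anti-VEGF array 2. Vegfa (-0.15, SE 0.12), Kdr (-0.87, SE 0.75) and Cpt1a (0.06, SE 0.16) did not pass. The count of genes was 1848 with array weights, 11 without anti-VEGF array 1, 4 without anti-VEGF array 2 and 628 without 4 arrays that stand apart.

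The treatment differences in the 2 livers were then compared. No gene passed the interaction in limma, with a smallest adjusted p of 0.278, and 677 had an unadjusted p under 0.05. The smallest p-values were those of Pou2f2 (1.25, SE 0.18), Cfap57 (-1.08, SE 0.16) and Klk1b11 (-1.63, SE 0.27), each with an adjusted p of 0.278. By camera 10 lists passed, and 0 with an estimated correlation (adjusted p = 0.66 to 0.69) or by fry. Interferon response genes differed less with treatment in fatty than in healthy liver, with a median difference of 0.60 (camera adjusted p = 9.44e-09; adjusted p = 0.69 with an estimated correlation), and T and NK cell genes more, with -0.75 (camera adjusted p = 3.59e-05; adjusted p = 0.69 with an estimated correlation), a call lost without fatty liver anti-VEGF array 3, when the median was -0.10. Without fatty liver anti-VEGF array 1 the median for interferon was 0.32 and that for T and NK cells -1.16, and without fatty liver vehicle array 2 the latter was -0.50. Across the 13286 genes, which are not independent replicates, the treatment differences in the 2 livers, which share no array, had a Pearson r of 0.308 and a Spearman rho of 0.249, with exact permutation p = 0.57 and 0.59 over the 400 assignments of arrays (two-sided). The sign was the same for 58.3% of genes. The count for the interaction was 1477 with array weights and 486 without 4 arrays that stand apart.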

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

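The tests of vehicle array 2, of immune markers, of Xist and Y-linked genes and of the interferon list were chosen after the results had been seen, and those of host cells on array 2, of the tumour share and of fewer macrophages replaced earlier forms whose results were known; the counts over other splits of the arrays were planned.

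The treatment difference was unlike in the 2 livers for 10 lists by camera's interaction test at its preset correlation, none with an estimated one. Median interaction differences on the log2 scale were 0.60 for interferon response, 0.79 for fibroblasts and matrix, 0.31 for cholesterol synthesis, 0.28 for the cell cycle, 0.29 for fatty acid synthesis, 0.36 for macrophages and 0.72 for endothelial cells. They were -0.75 for T and NK cells, -0.26 for hepatocytes and -0.027 for hypoxia response. The T and NK cell list lay near the limit in healthy liver, which left little room for a fall there. Of these calls, only those of interferon response and cholesterol synthesis held with each array left out in turn. Over those fits the medians ranged from 0.32 to 0.86 for interferon response, 0.14 to 0.45 for cholesterol synthesis, -1.16 to -0.10 for T and NK cells and -0.39 to 1.32 for endothelial cells. They ranged from 0.36 to 1.25 for fibroblasts and matrix, 0.09 to 0.54 for macrophages, 0.11 to 0.41 for the cell cycle, 0.16 to 0.37 for fatty acid synthesis, -0.37 to -0.07 for hepatocytes and -0.23 to 0.00053 for hypoxia response. Rows of the table without a single gene name, which the comparisons above do not use, also differed: in limma fits of those 8386 rows, 1325 passed between livers under vehicle, 1230 under anti-VEGF and 2 with treatment in healthy liver.

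Regrouping the 6 arrays of a pair of groups gives 10 splits, too few for a share under 0.05. Between livers, 6595 genes passed under vehicle and 6084 under anti-VEGF in the real grouping, reached by 1 of 10 splits each, and the highest other split had 0 in both. Of the 4 splits under vehicle that part all 3 same-numbered pairs, the others called 0 genes, as did the 6 that part 1 pair. With treatment, 0 genes passed in healthy liver and in the highest other split, so 10 of 10 reached it, and in fatty liver 1 gene against 0, reached by 1 of 10. List counts were 8 against a highest other of 15 for treatment in healthy liver (reached by 10 of 10), 6 against 13 in fatty liver (7 of 10), 12 against 20 between livers under vehicle (5 of 10) and 10 against 13 under anti-VEGF (4 of 10). For the interaction, the real count of 0 genes is reached by all 100 splits drawn whatever they hold, with a highest other of 12. Of those splits 67 reached the 10 lists called, with a highest other of 20, so chance is not excluded for the lists. The split with 12 genes kept the real healthy liver groups and joined fatty liver vehicle array 1 to anti-VEGF arrays 2 and 3. The cause of its calls was not tested.

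The first pattern weighed is vehicle array 2 of healthy liver, which stood apart from the other healthy liver arrays. Its endothelial list mean exceeded the highest fatty liver array by 1.34 and the highest other healthy liver array by 3.12. This test cannot decide on a swap with a fatty liver array, because the value lay outside both livers' ranges. More host cells in the sample are a candidate explanation: its mean of 3 Y-linked genes, 6.79, exceeded by 1.78 the highest of the 3 other healthy liver arrays low in Xist, all of which are anti-VEGF arrays. A swap, or a wrong label involving a sample outside the series, stays open, and no biological explanation was tested.

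The second pattern is the higher level of immune cell markers in tumours of fatty liver, other than those of B and plasma cells, which went both ways. Hepatocytes in the samples are argued against by Alb, Apoa1 and Ttr, transcripts abundant in hepatocytes, whose largest rise was 0.056 and of which Alb stayed at or below 4.07. Host sex is argued against by the 6 anti-VEGF arrays, none high in Xist, among which the macrophage list differed by 2.06. For a lower share of tumour cells as the only cause the values conflict. The macrophage list rose further than the mean of the endothelial, pericyte and fibroblast lists. The excess was 2.14 under vehicle (largest SD of a group 0.751) and 1.85 under anti-VEGF (0.661). That was beyond a bound of 2 SD that was set after these values were known, and not beyond 3 SD. On the vehicle arrays high in Xist, however, Xist rose by 2.25, the macrophage list by 2.02 and the T and NK cell list by 2.51. On the anti-VEGF arrays Y-linked genes rose by 2.73, the macrophage list by 2.06 and the T and NK cell list by 1.74. The macrophage list thus rose no further than these host transcripts. A lower tumour share alone, more immune cells in the fatty liver, or both stay open. The falls of cell cycle, sterol and fatty acid synthesis genes were not tested against the tumour share.

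The third pattern is the lower interferon response list under anti-VEGF in healthy liver. Fewer macrophages in the treated tumours cannot be told apart from a fall in the response itself: the interferon list fell further than the macrophage list, a difference of -0.42, which is within 2 of the largest SD of 0.254. An earlier form of this test, without vehicle array 2, had argued against fewer macrophages and was replaced after its result was seen. Host sex cannot be told apart either, because 1 vehicle array of healthy liver was low in Xist; its interferon mean lay 1.20 above the anti-VEGF mean, but its mean relative to macrophages was -0.99, near the -1.09 to -1.14 of the anti-VEGF arrays. The treatment itself stays open as untested apart from these.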

How the results depend on the processing

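Leaving out arrays that stand apart or are high in Xist, averaging near-identical ones, the fibroblast covariate and the block in the vehicle arrays alone were chosen after seeing the data; the other alternatives were planned. For treatment in healthy liver (0 genes), counts were 7 with centred arrays, 9 with trended robust eBayes, 9 at adjusted p under 0.10, 1661 with array weights, 47 in the 2 groups alone, and 417 with the hepatocyte covariate. They were 3 without both vehicle arrays numbered 2, 1185 when these were left out of the 2 groups alone, 1380 without 4 arrays that stand apart, 754 without those high in Xist and 16 with the fibroblast covariate. Without the arrays numbered 2, all vehicle arrays left are high in Xist and no anti-VEGF array is, so host sex and treatment cannot be told apart. For treatment in fatty liver (1 gene) the count was 1848 with array weights. It was 0 in the 2 groups alone, with the replicate block, with the hepatocyte covariate, averaged over livers, with near-identical arrays averaged and without those high in Xist. It was 5 without the arrays numbered 2, 2 in the 2 groups alone without them, 628 without 4 arrays and 6 with the fibroblast covariate. Between livers, under vehicle (6595) and anti-VEGF (6084), they were 3790 and 3294 with a fold of at least 1.5, 1074 and 3004 with the hepatocyte covariate, and 721 and 510 with near-identical arrays averaged, which leaves fewer samples. Under vehicle 1057 passed without the arrays high in Xist, which leaves 1 vehicle array per liver, assumed in every count without them to vary like the anti-VEGF groups, and under anti-VEGF 9884 with array weights. The interaction (0) gave 1477 with array weights, 43 with the hepatocyte covariate, 3 without the arrays numbered 2, 486 without 4 arrays and 19 without those high in Xist. List counts became 0 with an estimated correlation in all 5 contrasts, and 0 by fry for both treatment contrasts and the interaction. For treatment in healthy liver (8 lists) they were 5 with array weights, 5 without the arrays numbered 2 and 14 without those high in Xist. In fatty liver (6) there were 10 without those high in Xist and 14 with the fibroblast covariate, and for the interaction (10) there were 6 with array weights. The correlation of treatment differences (0.308) became -0.164 with the hepatocyte covariate. Without the arrays numbered 2 it was 0.168, past the threshold, but there Xist and treatment coincide. Leaving out each replicate gave 0 to 41 genes for treatment in healthy liver, 0 to 11 in fatty liver, 4689 to 7337 and 4274 to 7475 between livers, 0 to 0 for the interaction, and r from 0.073 to 0.390. Lists ranged from 6 to 11, 5 to 9, 12 to 14, 8 to 11 and 9 to 13 in the same order. The hepatocyte list, driven by Arg1 and Hp, turned the sign of the vehicle liver difference for Cxcl3 (-0.0102), Pfkm (0.11), Eno2 (0.0857), Cpt2 (0.0101), Kdr (-0.35), Hp (-0.64) and Slc2a1 (0.0488). With 8 of its 34 genes measured and Alb below the limit, that list is no clear measure of hepatocytes. Where arrays were left out or averaged there were fewer samples; for the other changes the cause was not tested. Counts of genes and lists under the other alternatives stayed within 1.5 times. Of single-gene results over all alternatives, 18243 kept direction and side of the threshold, 708 lost the threshold and 550 passed it. Direction changed for 251 that had not passed in the main fit and for 7 that had. Apart from fatty liver treatment, the replicate block changed no count by over 1.5 times. For pairs of groups other than the vehicle groups the replicates share only a number. Over all pairs of groups, the vehicle groups included, 7 of 18 same-number correlations were over 0.1, from -0.486 to 0.701. Of the 126 named genes past the threshold between livers under vehicle, 106 passed with each array left out and 25 with near-identical arrays averaged; under anti-VEGF these were 102 and 25 of 120. Values near the table's median limit what low genes can show, since no detection call was used.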

Other observations

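The test of clock genes was chosen after their values had been seen. Of 14 genes of the circadian clock, none passed over all genes tested in limma, with treatment averaged over livers or in either liver. In the averaged contrast, Nr1d1, a repressor of the clock, was higher under anti-VEGF by 0.70 on the log2 scale (SE 0.13), on all 3 treated arrays of each liver against all 3 vehicle arrays. Cry1, which represses the clock's activators, was lower by -0.49 (SE 0.08) on all treated arrays of each liver in the same sense, and Per1 was lower by -0.62 (SE 0.18), though its value on healthy liver vehicle array 2, 9.42, lay within the anti-VEGF arrays of that liver. Arntl, which Nr1d1 represses, was higher by 0.30 (SE 0.09) on all treated arrays of each liver, and Nr1d2 by 0.36 (SE 0.11). Adjusted over 14 clock genes, limma's p-values were 0.00163 for Nr1d1, 0.00109 for Cry1, 0.0244 for Per1 and Arntl and 0.0279 for Nr1d2, an adjustment that carries little weight because the genes were chosen from their values. Over all genes they were 0.146 for Nr1d1 and 0.119 for Cry1. The time of tissue collection is not given in the sources used here.

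Of 18 angiogenic factor genes 3 rose and 5 fell under vehicle and 3 rose and 4 fell under anti-VEGF, with camera adjusted p of 0.899 and 0.65. Without healthy liver vehicle array 2, 6 rose under vehicle. The list was thus not called between livers. The 2 measured cholangiocyte genes averaged 10.74 and 10.71 in healthy liver and 9.59 and 9.95 in fatty liver, under vehicle and anti-VEGF. Erythroid means were 6.34, 6.05, 6.81 and 6.55 and acinar pancreas means 5.03, 5.14, 5.16 and 5.23 in the order healthy vehicle, healthy anti-VEGF, fatty vehicle and fatty anti-VEGF.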
